A study of Mus musculus with 2 samples.

How the data were processed

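DNase-seq was measured in 2 libraries of kidney tissue from male adult B6CASTF1/J mice aged 18 to 20 months. Both belong to 1 group, kidney, from the tissue label, and their replicate numbers come from the labels. The labels state biological replicates but give both the same donor record.

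Per the labels, the files are on the mouse assembly mm10, which is GRCm38. The aligner, the peak and footprint callers, their versions and the filters are not given in the sources used here. Peaks and footprints were called by the authors separately in each library, per the deposited notes. Each library has 2 deposited peak lists in narrowPeak format, and the notes do not say which threshold separates them. Peak signal, in the deposited lists, is scaled per library by the authors to a total that is not stated. Its values were whole multiples of 1 step (within 0.05 of a step) for at least 99.9994% of peaks, with steps of 0.00426 in replicate 1 and 0.00724 in replicate 2. The per-position file holds a p-value type measure, a false discovery rate of the cut rate, per the deposited notes, and lists only positions below 0.05. The deposited footprints carry a p-value column with the same entry, 0.01, in every line, so footprints could not be ranked. Of the base pairs in the longer peak lists, 98.6% and 98.0% had a listed rate up to 0.05, and of those in the shorter lists 99.2% and 98.4% had a rate up to 0.001. The longer list is called the looser and the shorter the stricter one, and the looser list was the main set. The cell numbers, the cut totals and the share of cuts in peaks are not analysed here. Reads from a hybrid of 2 strains placed on the reference of 1 of them can be lost where the strains differ, which was not tested here.

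Coordinates were compared with the GRCm38 chromosomes. On 21 chromosomes no peak and none of 1852037 GENCODE M21 annotation lines ended past the chromosome end. Genes were the 21911 protein-coding genes of GENCODE M21 with a symbol used once, after leaving out 27 repeated ones. Positions are given counted from 1.

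Peaks of both libraries were compared by overlap of at least 1 bp in either direction and by base pairs in both sets over those in either. Chance overlap was taken from peaks moved by 100 kb along the chromosome, wrapping round its end. Shares have 95% exact Clopper-Pearson intervals, which cover counting error only. A promoter was the region within 1000 bp of the 5′ end of a gene. Genome shares of introns, exons and intergenic sequence came from 1000000 random positions, without assembly gaps. Pairs of overlapping peaks, with the strongest partner, gave the correlation of log2 signal.

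Gene lists (27, for renal cell types, other cell types, other organs, metabolism, development, Hox paralogs, clock and housekeeping) and 25 consensus motifs were fixed before the data were examined, as were the main tests and their alternatives. Further tests chosen after results were seen are named under Other observations. Of the list genes 1, Ahsp, was not among the genes used. For promoters, the number of members with a peak in both libraries was compared with 10000 random lists of the same size, drawn from genes in the same of 3 tertiles of promoter CpG observed over expected. For loci, the median number of peaks in the gene body and 10 kb on either side, as a mean of both libraries, was compared with random lists matched on 10 classes of gene length. Both are two-sided permutation tests with Benjamini-Hochberg adjustment over the 27 lists and a threshold of 0.05. Genes named in the text follow a rule set beforehand. Per list these were up to 3 members with a promoter peak in both libraries and the highest mean percentile of signal, up to 2 members with no promoter peak in either library in alphabetical order, the 10 strongest shared peaks and all motifs. Some genes that the rule gives are not reported here, and genes named at other transcript starts were chosen after their values were seen.

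Motif matches on both strands were counted where the match centre lay in a footprint, inside or outside a peak, and in the parts of the peaks of the same library that no footprint covers. A motif counted as denser at 1.5-fold or more in both libraries, with no test. For the false discovery rates, the mean −log10 value per 1 kb bin, with positions not listed at 0 and values limited to 300, was correlated between libraries. For chromosome X, signal of promoters with a peak was also compared with the 50 autosomal promoters nearest in CpG observed over expected, with 2000 bootstrap draws over X promoters. For gene lists, replicate 1 peaks found in replicate 2 were also compared with the number expected from 20 bins of signal, or from these and 5 bins of GC content, against 10000 random lists matched on gene length. GC content was taken from 150 bp around the peak centre.

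The list tests were tested on simulated data with 20000 genes and lists of 12. Lists with no effect gave p below 0.05 in 2% of 400 cases for promoters and 2.5% for loci. Opening 50% of the closed promoters was found in 40.5% of lists, and 2.5-fold more peaks in 69.8%, before adjustment. Overlaps in 50 of 50 simulated pairs of peak lists equalled a count base by base, and 100% of 1000 motif copies planted in simulated sequence were found.

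Alternatives were the stricter peak list, other promoter windows (500 and 2000 bp), any annotated transcript start, no matching, flanks of 50 kb, reciprocal overlap of 50%, the same number of top peaks, other bins and scales, other motif backgrounds, and each library alone. With n = 2 no test between libraries was made. Software was Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.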

Results

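DNase-seq reads out open chromatin from the places where the nuclease DNase I can reach and cut DNA. It was applied here to kidney tissue of male adult B6CASTF1/J mice, a hybrid of the C57BL/6J and CAST/EiJ inbred strains, aged 18 to 20 months. The series holds 1 group of n = 2 libraries, numbered as biological replicates 1 and 2. The libraries have separate biosample records but the same donor record, so the labels do not show whether they came from separate animals, and the spread between them may be technical. With a single group there is no contrast between conditions. The comparisons are therefore how far the libraries resemble each other and which genes, regions and sequence motifs are accessible within them.

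Replicate 1 had 169994 peaks covering 33.8 Mb, or 1.24% of the genome, and replicate 2 had 91750 peaks covering 18.6 Mb, or 0.681%. Median peak width was 200 and 201 bp. Footprints, short protected stretches inside accessible DNA where a bound protein blocks cutting, numbered 510170 and 231369, with median widths of 10 and 9 bp. The total number of cuts was not analysed here. Peak signal was a whole multiple of 1 step in each library, and that step was 1.70 times larger in replicate 2, which corresponds to 1.70 times fewer cuts in replicate 2 if both were scaled to the same total.

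Strong accessible sites were shared between the libraries and weak ones were mostly found in replicate 1 alone. Of the replicate 2 peaks, 90.9% (95% exact binomial interval 90.7 to 91.1%) overlapped a replicate 1 peak by at least 1 bp, whereas 49.0% (48.8 to 49.3%) of replicate 1 peaks overlapped a replicate 2 peak. After moving the replicate 2 peaks by 100 kb along each chromosome these shares were 4.86% and 2.63%. In replicate 1 the overlapping share was 5.39% in the lowest decile of peak signal and 98.8% in the highest, and in replicate 2 it was 59.8% and 99.7%. Base pairs in both peak sets made up 39.1% of those in either. Over 83361 shared peaks, log2 signal correlated with Pearson's r = 0.905 and Spearman's rho = 0.883 across peaks, which are not independent replicates. The median log2 ratio of replicate 1 over replicate 2 was 0.46 with an SD of 0.59 over peaks. These intervals cover counting error only.

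**Figure D1:**
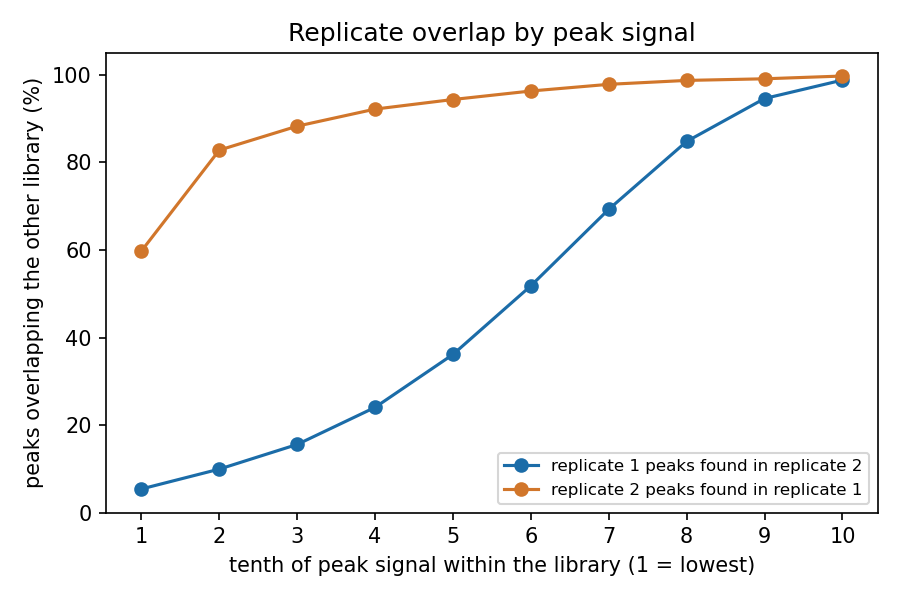
Share of peaks that overlap a peak of the other library (%, vertical axis) by decile of peak signal within each library (horizontal axis, 1 is the lowest), one line per library. The replicate 1 line runs from 5.39% to 98.8%, and the replicate 2 line from 59.8% to 99.7%.

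Accessible sites were concentrated at promoters. Within 1000 bp of the 5′ end of a protein-coding gene lay 15.3% of replicate 1 peaks and 23.1% of replicate 2 peaks, a mean of 19.2% ± 5.53 (SD, n = 2), while these windows held 1.52% of the genome. By peak centre, 38.7% ± 2.67 of peaks lay in introns, 36.1% ± 2.80 between genes and 6.78% ± 0.0236 in exons (SD, n = 2), against 35.1%, 60.1% and 3.27% of random genome positions. Promoter peaks had a median signal of 1.63 ± 0.0636 and intergenic peaks 0.585 ± 0.115 (SD, n = 2). A promoter peak was present in both libraries for 13179 of 21911 protein-coding genes (60.1%). This share rose with CpG content, from 14.3% of genes in the lowest tertile of promoter CpG observed over expected to 72.9% in the middle and 93.3% in the highest.

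The peak with the highest mean rank in both libraries lay on chromosome 17 at 39846781 to 39846900 (GRCm38), with signals of 56.2 and 55.6 in replicates 1 and 2, inside a ribosomal RNA gene of the GENCODE annotation that RefSeq lists as the pseudogene Rn18s-rs5. The next, on chromosome 3 at 5860341 to 5860520, had signals of 62.7 and 33.3 and overlapped no annotated gene. On chromosome 15 a peak in an exon of Cers5, a ceramide synthase gene, at 99735641 to 99735920 had signals of 29.4 and 42.5. An intergenic peak on chromosome 3 at 88178021 to 88178220, whose nearest protein-coding gene was Mef2d, had signals of 23.8 and 30.1. The other 6 of the 10 strongest shared peaks were promoter peaks, at Rfx1, Bahcc1, Hnrnpc, Ankhd1, Ip6k1 and Ppm1k. Their signals ranged from 22.8 to 28.9 in replicate 1 and from 20.6 to 28.1 in replicate 2. Multi-copy sequence, such as ribosomal DNA, can collect cuts from several copies at 1 position.

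Genes in 4 of 5 renal tubule lists had open promoters more often than genes matched on promoter CpG, though 3 of the 4 did not pass in the stricter peak lists. Of 20 proximal tubule genes, which serve reabsorption of filtered solutes and proteins, 15 had a promoter peak in both libraries, against a mean of 8.77 in random matched lists (adjusted permutation p = 0.00432). For the loop of Henle the count was 11 of 12 against 6.21 (0.00432), for collecting duct principal cells 9 of 11 against 5.06 (0.0273) and for intercalated cells 8 of 10 against 4.20 (0.0112). Among the proximal tubule genes, the endocytic receptor gene Lrp2 had promoter signals of 5.60 and 5.29 in replicates 1 and 2, the fatty acid transporter gene Slc27a2 4.56 and 4.41, and Cyp4b1 5.83 and 3.20. Umod, the gene of the urinary protein uromodulin, had 4.17 and 2.41, and the sorting receptor gene Sorl1 2.31 and 2.06. In the principal cell list the transcription factor gene Tfcp2l1 had 6.10 and 3.98, the sodium channel subunit gene Scnn1g 4.45 and 2.59, and the water channel gene Aqp3 2.09 and 1.21. The proton pump subunit gene Atp6v1b1 had 0.942 and 1.35. No promoter peak was called in either library for Slc22a8, Aqp6 or Slc4a1. The distal convoluted tubule list had 6 of 8 promoters open against 4.08 (adjusted permutation p = 0.338), with the kinase gene Wnk4 at 4.74 and 3.41 and the thiazide-sensitive cotransporter gene Slc12a3 at 1.18 and 1.26. The podocyte list had 7 of 10 against 7.12 (adjusted permutation p = 1), with Cdkn1c at 4.81 and 3.45, Magi2 at 1.51 and 1.22, and no promoter peak at Nphs1 or Ptpro.

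All p-values for gene lists are two-sided, come from 10000 random lists and are Benjamini-Hochberg adjusted over 27 lists. They describe these libraries, since genes are not replicates. The higher tubule counts rested on the CpG matching: against unmatched genes the adjusted permutation p was 0.365 for the proximal tubule, 0.0733 for the loop of Henle, 0.341 for principal cells and 0.433 for intercalated cells. In the stricter peak lists the principal and intercalated cell counts lay below the random mean, at 4 and 3 (adjusted permutation p = 1 and 0.744), and the loop of Henle count of 8 no longer passed (0.310). Intercalated cells also did not pass without replicate 2 (8, permutation p = 0.0667) or with any transcript start (0.0510), nor principal cells with a window of 500 bp (8, 0.0867). Over the 7 alternatives the adjusted p ranged from 0.0009 to 0.365 for the proximal tubule, 0.00135 to 0.310 for the loop of Henle, 0.00135 to 1 for principal cells and 0.00648 to 0.744 for intercalated cells.

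**Figure D2:**
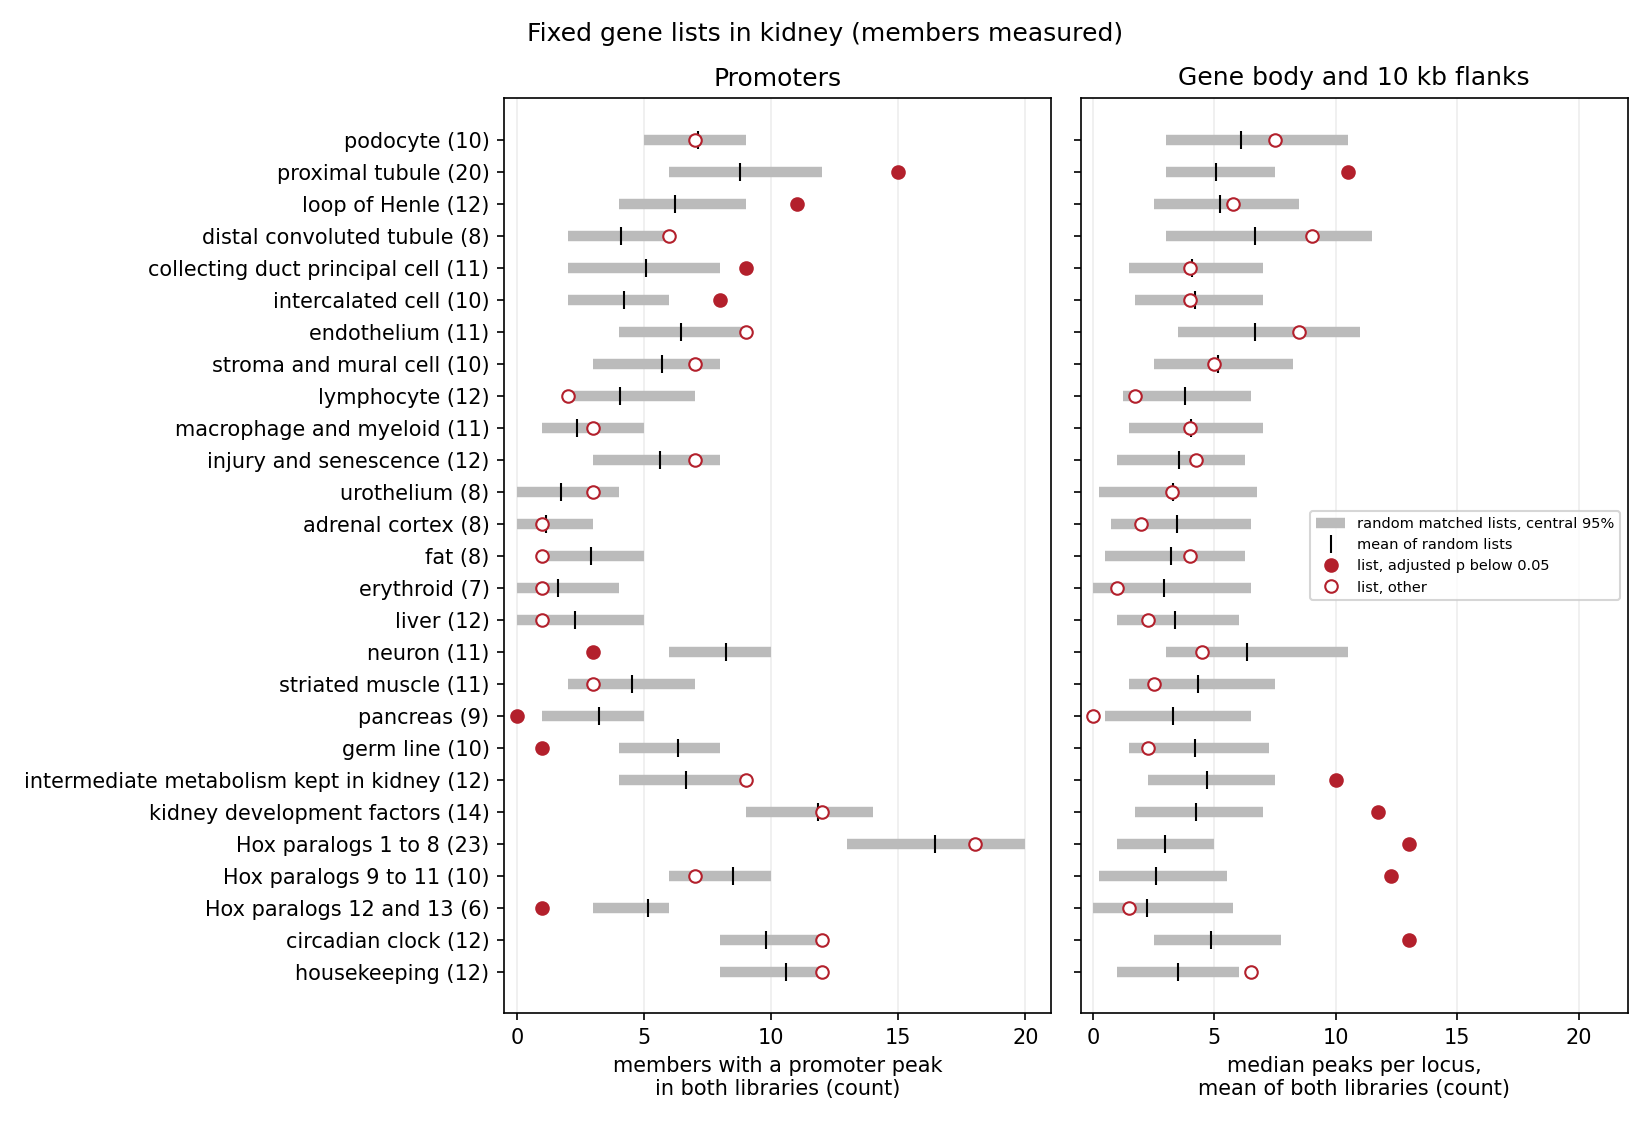
Number of list members with a promoter peak in both libraries (left) and median number of peaks per gene locus, averaged over both libraries (right), for each fixed list with its number of measured members. Grey bars span the central 95% of 10000 random matched lists and ticks mark their mean; filled points have an adjusted p below 0.05, such as the proximal tubule with 15 open promoters and 10.5 peaks per locus.

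Proximal tubule, metabolic, developmental and clock genes also carried more peaks along their loci than genes of like length. The median number of peaks in the gene body and 10 kb on either side was 10.5 for the proximal tubule list against a mean of 5.06 in random lists (adjusted permutation p = 0.00054). It was 10 for a list of metabolic genes active in kidney, which also holds vitamin D genes and a water channel gene (4.70, permutation p = 0.0027), 11.8 for transcription factor and signalling genes of kidney development (4.24, p = 0.00054) and 13 for the circadian clock (4.88, p = 0.00054). The value 0.00054 follows from 0.0001, the smallest p that these permutations can give. Promoter signals in the metabolic list were 28.2 and 8.75 at the nuclear receptor gene Esrra, and 10.7 and 9.77 at Ppara. The promoters of 9 of 12 metabolic genes were open in both libraries against 6.63 (adjusted permutation p = 0.212), with 11 open and p = 0.0212 with any transcript start and 10 open and p = 0.0327 in replicate 2 alone. Those of 12 of 14 developmental genes were open against 11.8 (permutation p = 1). In the developmental list Pax8 had 6.07 and 6.06, Pou3f3 6.80 and 5.43, and Lhx1 5.09 and 4.08. All 12 clock genes had open promoters in both libraries (random mean 9.79, adjusted permutation p = 0.159, and 0.0275 without CpG matching), with 20.8 and 25.4 at Dbp, 22.5 and 16.4 at Per1 and 23.6 and 14.2 at Nr1d1. The locus calls of the proximal tubule and developmental lists rested on replicate 1: without it the medians were 6 and 5.50 (adjusted permutation p = 0.128 and 0.155). With flanks of 50 kb both calls ended as well (permutation p = 0.0801 and 0.191), and in the stricter peak lists that of the proximal tubule (0.0636).

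Hox genes, which pattern the body axis and lie in 4 clusters, carried many peaks at paralogs 1 to 11. The loci of paralogs 1 to 8 and 9 to 11 had medians of 13 peaks (17 in replicate 1 and 9 in replicate 2) and 12.2 peaks (19.5 and 6), against 2.99 and 2.60 in random lists (adjusted permutation p = 0.00054 for both), whereas paralogs 12 and 13 had 1.5 against 2.23 (p = 0.889), a median that rose to 20 with flanks of 50 kb (adjusted permutation p = 0.0801). The difference between these lists was not tested. Promoters were open in both libraries for 18 of 23 paralogs 1 to 8 (random mean 16.4, adjusted permutation p = 0.541) and 7 of 10 paralogs 9 to 11 (8.50, p = 0.332), the latter falling to 4 with p = 0.0243 in the stricter peak lists. Of the 6 paralogs 12 and 13, 1 promoter was open, that of Hoxc13, against a random mean of 5.18 (permutation p = 0.00135). Hoxa5 had promoter signals of 5.10 and 7.45, Hoxb4 6.46 and 4.75, Hoxd10 4.68 and 3.32, Hoxd9 3.48 and 3.80, and Hoxc13 1.28 and 1.66, while Hoxa13 and Hoxc12 had no promoter peak. Neighbouring Hox genes share peaks, so these locus p-values are too small. Without CpG matching the count for paralogs 12 and 13 had an adjusted permutation p of 0.0800, and in replicate 1 alone it was 2 (0.0018).

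For genes of other cell types that kidney tissue can hold, no difference from matched genes was detected. The endothelial list had 9 of 11 promoters open in both libraries against a random mean of 6.45 (adjusted permutation p = 0.187, and 11 open with p = 0.0121 with any transcript start), with the endothelial receptor gene Flt1 at 2.63 and 2.57 and Ehd3 at 5.28 and 1.88. Stroma and mural cells had 7 of 10 against 5.72 (permutation p = 0.541), with the collagen gene Col1a1 at 4.47 and 1.32 and no promoter peak at the renin gene Ren1. Lymphocytes had 2 of 12 against 4.05 (permutation p = 0.332), macrophages and myeloid cells 3 of 11 against 2.35 (p = 0.7495), and genes of injury and senescence 7 of 12 against 5.62 (p = 0.541). The injury list included Clu at 3.70 and 2.60 and Krt8 at 3.20 and 1.71, and no promoter peak at Cdkn1a or Krt20. In replicate 1 alone the count was 7 of 11 for macrophages (adjusted permutation p = 0.0441), 4 of 12 for lymphocytes (0.774) and 2 of 8 for fat (0.332), and in replicate 2 alone 2 of 7 for erythroid cells (1). Urothelium had 3 of 8 against 1.73 (permutation p = 0.476), adrenal cortex 1 of 8 against 1.14 (p = 1), fat 1 of 8 against 2.90 (p = 0.332) and erythroid cells 1 of 7 against 1.60 (p = 0.7495). Against unmatched genes, the lymphocyte, fat and adrenal counts were lower (adjusted permutation p = 0.0175, 0.0287 and 0.0287). Housekeeping promoters were open for all 12 genes against 10.6 (permutation p = 0.531, and 0.0287 against unmatched genes), with Rplp0 at 19.7 and 8.62.

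Promoters of genes used in distant organs were closed more often than matched promoters in 3 of 5 such lists. None of 9 pancreas genes had a promoter peak in both libraries against a random mean of 3.25 (adjusted permutation p = 0.0270), 1 of 10 germ line genes did against 6.34 (p = 0.0018) and 3 of 11 neuronal genes against 8.24 (p = 0.00135). The germ line exception was Dazl, an RNA-binding protein gene, with promoter signals of 4.05 and 2.997, and the open neuronal promoters were those of Snap25 (2.08 and 1.63), Syn1 (1.90 and 1.04) and Elavl4 (0.554 and 0.565). Liver had 1 of 12 against 2.30 (permutation p = 0.541, and 0.00675 against unmatched genes), with 3 open in replicate 1 and 2 in replicate 2, the gene open in both being the fibrinogen chain gene Fga at 1.74 and 1.61, and striated muscle 3 of 11 against 4.51 (permutation p = 0.465), with the creatine kinase gene Ckm at 3.81 and 1.64. The neuronal and pancreatic calls rested on replicate 2: replicate 1 alone had 8 of 11 neuronal promoters open (adjusted permutation p = 0.771) and 1 of 9 pancreatic ones (p = 0.0911). The pancreatic call ended in the stricter peak lists (0.0606) and with any transcript start (0.334), and the neuronal one against unmatched genes (0.0733). The insulin gene Ins2 counted as closed at its annotated 5′ end. At 7 of its 8 other starts it had a peak in both libraries, with signals of 1.24 and 0.528 at a start 63.8 kb away. The germ line count stayed below 0.05 under all 7 alternatives, with adjusted permutation p-values from 0.0009 to 0.0144. Matching was by CpG tertile only, and differences in CpG within a tertile were not adjusted for. Some members lay just above the lower bound of the middle tertile, 0.278, such as Pnlip (0.281), Stra8 (0.291) and Gad1 (0.291). For the 21 lists that did not pass the test of peaks per locus, medians ran from 0 in the pancreas list to 9 in the distal convoluted tubule list, and housekeeping genes passed in the stricter peak lists (adjusted permutation p = 0.0229).

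At Hnf4a, the gene of a nuclear receptor of the proximal tubule, no peak lay within 1000 bp of the annotated 5′ end at position 163506808 of chromosome 2 in either library, although the locus held 25 and 14 peaks. A transcript start 40.0 kb downstream, at 163546817, carried a peak with signals of 4.80 and 4.47.

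**Figure D3:**
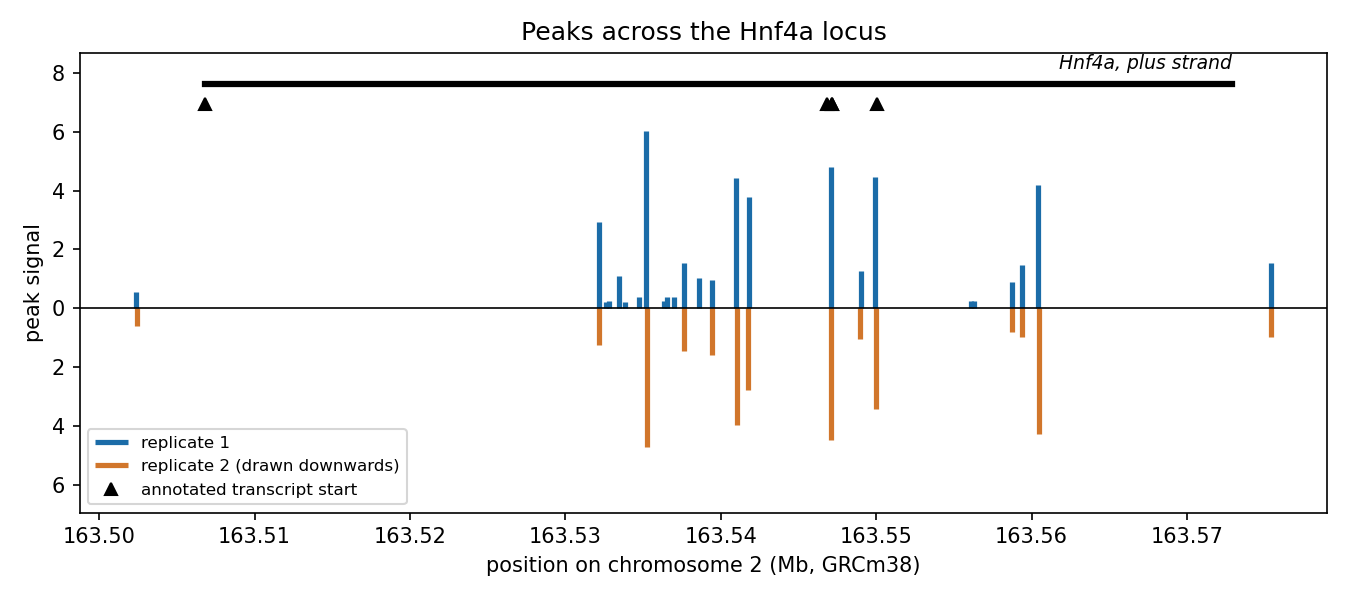
Peaks across Hnf4a and 10 kb on either side on chromosome 2 (horizontal axis, Mb, GRCm38), with peak signal upwards for replicate 1 and downwards for replicate 2. The black bar is the gene and triangles are annotated transcript starts; the start at 163546817 has signals of 4.80 and 4.47 and the 5′ end at 163506808 has none.

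Binding motifs of HNF4, HNF1, ESRR and RXR were denser in footprints than in the rest of the peaks, whereas FOX and GATA, to which factors of the renal gene lists also belong, were not. The string used for the GRHL and TFCP2 family, AACCGGTT, was not denser in both libraries either. Whether it marks sites of Tfcp2l1 was not tested. Motif matches per kb were 4.69-fold ± 0.302 denser for HNF4 (CAAAGTCCA), 3.57-fold ± 0.607 for HNF1 (GTTAATNATT), 2.01-fold ± 0.0233 for ESRR and 6.35-fold ± 2.08 for the RXR direct repeat (SD, n = 2). The size depended on how a match was counted: with the whole match inside the footprint the mean was 9.29 ± 2.48 for HNF4, 7.11 ± 1.78 for HNF1, 2.66 ± 0.503 for ESRR and 19.6 ± 10.2 for the RXR repeat, and in the stricter peak lists it was 16.6 ± 12.8 for the RXR repeat (SD, n = 2). All footprints were counted, of which 85.0% and 89.9% lay in peaks. Among general factors the values were 113 and 66.0 in replicates 1 and 2 for NRF1, 20.1 and 17.8 for CREB and ATF, 20.0 and 8.28 for SP and KLF, 19.4 and 6.51 for NFI, 7.19 and 5.31 for RFX, and 6.99 and 9.89 for ETS, while NFY had 2.09 and 4.08. The NRF1 values divide by a small background, 0.000577 and 0.00216 matches per kb in the rest of the peaks. Those of the RXR repeat rest on 103 and 22 matches in footprints. Counting error of the matches is not covered by the SD of these folds. CTCF (CCASYAGRKGGC), which shapes chromatin loops, had 38.1 and 5.07, from 6143 and 1686 matches in footprints. With the whole match inside, the means were 76.9 ± 90.9 for CTCF, 273 ± 98.0 for NRF1, 47.0 ± 31.6 for NFI, 41.6 ± 1.97 for CREB and ATF, 33.8 ± 19.6 for SP and KLF, 18.5 ± 10.8 for ETS, 13.3 ± 0.811 for RFX and 5.92 ± 4.09 for NFY, and in the stricter peak lists 34.0 ± 39.8 for CTCF and 74.8 ± 92.2 for NFI (SD, n = 2). In all, 12 of 25 motifs were at least 1.5-fold denser in both libraries. Of the others, IRF (1.08 and 2.84), MEF2 (0.501 and 1.63) and the GRHL and TFCP2 family (1.69 and 0.783, from 71 and 15 matches in footprints) passed 1.5 in 1 library. The remaining motifs passed it in neither: AP-1 (0.904 and 1.03), TEAD (0.855 and 1.40), posterior HOX (0.986 and 1.22), SRF (0.932 and 1.13), the glucocorticoid and androgen receptors (1.11 and 1.31), PU.1 (0.626 and 1.04), SOX (0.894 and 0.772), RUNX (0.727 and 0.542), GATA (0.431 and 0.814) and FOX (0.241 and 0.841). Against the reversed consensus in the same footprints, AP-1, TEAD, posterior HOX and the glucocorticoid and androgen receptors also passed 1.5 in both libraries. So did PU.1, SOX, GATA and MEF2. AP-1 had 1.89 and 2.22 and TEAD 7.46 and 6.10. The GRHL and TFCP2 family fell to 0.227 and 0.107, the only motif sparser in both by over 1.5-fold. Those values compare 71 and 15 matches with 313 and 140 of the reversed string in replicates 1 and 2. Reversing this string removes its CpG and produces both ends of the NFI string, a motif dense in footprints. The low values therefore cannot show that sites of this family are depleted in footprints. With the whole match inside the footprint and the rest of the peaks as background, 2 motifs were sparser by over 1.5-fold in both libraries.

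Some of the motifs divided between promoters and the rest of the genome. In footprints away from promoters, matches per kb over those in promoter footprints were 10.6 ± 2.33 for the glucocorticoid and androgen receptors, 9.88 ± 1.40 for CTCF, 5.92 ± 0.617 for NFI, 5.87 ± 0.182 for HNF4, 5.55 ± 0.817 for HNF1, 4.34 ± 0.183 for AP-1 and 3.70 ± 0.0310 for TEAD (SD, n = 2). The value for the glucocorticoid and androgen receptors rests on 11 and 5 matches in promoter footprints of replicates 1 and 2. That of NFI rests on 12 and 4, and that of CTCF on 238 and 81. The SD does not cover this counting error, so the order of these motifs is uncertain. The ratio was 0.122 ± 0.0209 for ETS, 0.153 ± 0.00519 for SP and KLF, 0.159 ± 0.00168 for NRF1 and 0.278 ± 0.0746 for NFY. Other motifs divided less, with 1.06 and 0.952 in replicates 1 and 2 for IRF, 0.879 and 0.747 for RFX and 1.65 and 1.07 for SRF. Consensus strings also differ in base composition, as do promoters and other sites, and a string marks a possible site and not a bound protein.

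**Figure D4:**
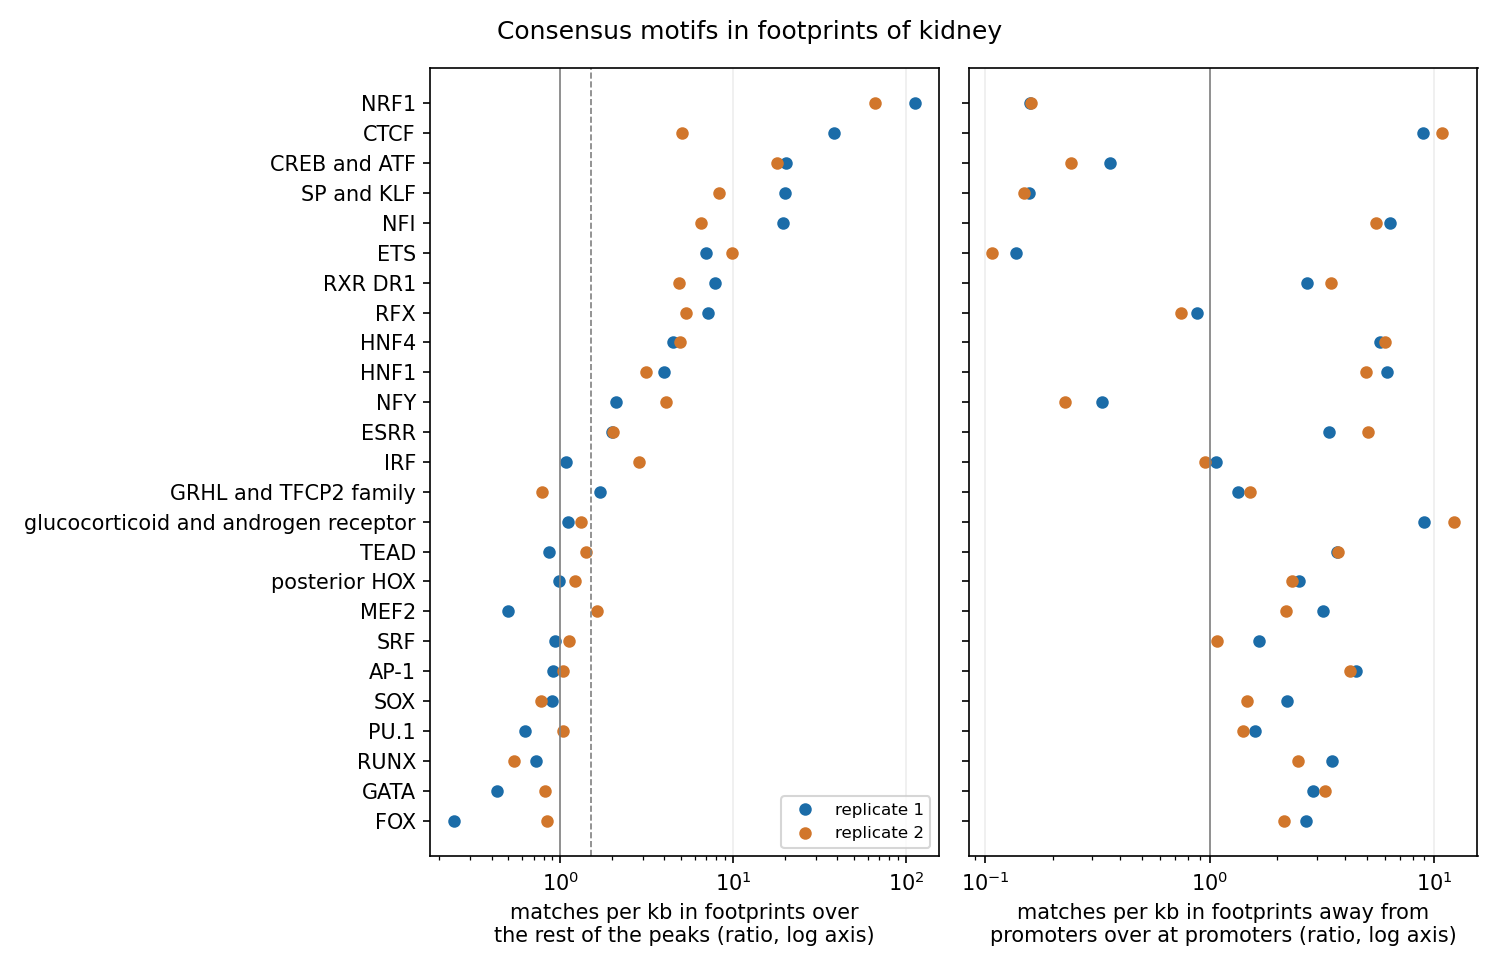
Motif matches per kb in footprints over those in the rest of the peaks (left, ratio on a log axis, dashed line at 1.5) and in footprints away from promoters over those at promoters (right, ratio on a log axis), one point per library. HNF4 lies at 4.48 and 4.91 on the left and at 5.74 and 6.00 on the right, while ETS lies at 0.137 and 0.108 on the right.

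Footprints were shared less than peaks. Of replicate 2 footprints, 58.2% overlapped a replicate 1 footprint by at least 1 bp, and 23.8% of replicate 1 footprints overlapped one of replicate 2. Inside shared peaks 61.0% of replicate 2 footprints overlapped, against 42.8%, 34.3% and 22.2% after moving them by 20, 50 and 100 bp. With an overlap of at least 50% of both footprints required, the shares were 26.7% and 12.1%.

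Chromosome X, present in 1 copy in males, carried fewer and weaker peaks than the autosomes. Replicate 1 had 25.3 peaks per Mb on X and 67.2 on the autosomes, and replicate 2 had 12.9 and 36.3, a mean ratio of 0.365 ± 0.0150 (SD, n = 2). Per protein-coding gene the ratio was 0.556 ± 0.0229. Median peak signal on X was 0.333 against 0.614 on the autosomes in replicate 1, and 0.492 against 0.804 in replicate 2. Chromosome Y had 144 and 88 peaks.

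Per-position false discovery rates correlated between the libraries, though many bins had a listed position in only 1 of them. Positions with a listed rate, all below 0.05, covered 56.9 Mb in replicate 1 and 29.9 Mb in replicate 2. Over 202048 bins of 1 kb with a listed position in either library, the mean −log10 rate per bin correlated with Pearson's r = 0.878 and Spearman's rho = 0.754 across bins, which are not independent replicates. Of these bins, 104482 had a listed position in both libraries.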

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

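None of the alternatives was chosen after a result was seen. The shares of overlapping peaks moved with every alternative, while the share of base pairs does not depend on the reciprocal rule. In the stricter lists 94.7% of replicate 2 peaks and 47.5% of replicate 1 peaks overlapped, with 38.5% of base pairs shared. A reciprocal overlap of 50% gave 72.6% and 39.2%, and the same number of top peaks 77.1% and 76.9%, with 50.03% of base pairs. Footprints overlapped in 26.7% and 12.1% with a reciprocal overlap of 50%, and in 61.0% and 42.6% inside shared peaks, with 25.5% of base pairs. The same number of footprints from each library could not be taken, because every footprint has the same value. The promoter share was 26.8% ± 6.14 with any transcript start, a wider target. Its mean stayed within 1 SD of 19.2% with other windows, the stricter lists and the same number of top peaks. That SD is the spread between the libraries and hides shifts within each. In replicates 1 and 2 the share was 18.9% and 29.7% in the stricter lists. It was 11.2% and 18.0% with 500 bp, and 19.6% and 27.5% with 2000 bp. The same number of top peaks gave 21.3% and 23.1%, with an SD of 1.28 (n = 2). With the main settings single libraries had 15.3% and 23.1%, which with n = 2 always lie within 1 SD of their mean. The X to autosome ratio was 0.337 in the stricter lists and 0.556 per gene, and 0.354 to 0.376 in single libraries. The correlation of false discovery rates was 0.877 in bins with a peak, 0.860 in 10 kb bins and 0.893 on a log2 scale.

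Promoters passed the test in 8 lists, in 5 with the stricter peak lists, and in 6 to 9 in single libraries. Principal and intercalated cells turned from above to below the random mean in the stricter lists, at 4 and 3 open promoters; the cause was not tested. Of 189 list values under the promoter alternatives, 162 kept their side of the threshold, 14 lost the call, 11 gained it and 2 turned. In 19 cases a list that did not pass lay on the other side of the random mean, again without passing. Without CpG matching 6 lists lost the call and 6 gained it, including lymphocyte, liver, fat and adrenal genes. For peaks per locus 6 lists passed, 4 with flanks of 50 kb and 4 to 6 in single libraries, and 129 of 135 values kept their side of the threshold, 14 of them on the other side of the random mean without passing. Against the reversed consensus 19 motifs passed the threshold rather than 12. That ratio leaves out the rest of the peaks, so it cannot show density in footprints relative to them. In single libraries 13 to 14 motifs were dense. Of 124 single motif values 44 moved, 22 against the reversed consensus, 16 with the whole match inside and 6 in the stricter lists. Those settings left 2, 9 and 19 unmoved. The 25 values of each single library were counted as unmoved without a comparison. NFI has no value against the reversed consensus, since replicate 2 had no reversed match. Weak sites were the least shared: 5.39% of the lowest decile of signal in replicate 1 overlapped replicate 2, and whether depth is the cause was not tested.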

Other observations

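The tests by decile of signal, by window, of peaks of the same signal, of promoters matched on CpG and of other transcript starts were chosen only after the results were seen, as was the depth test of AT-rich peaks.

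Some list genes without a peak at their annotated 5′ end were open at another start, in renal and in other lists. Of 94 list members with no peak at the 5′ end in either library, 46 have another annotated start over 1000 bp away, and 15 of these (32.6%) had a peak there in both libraries, against 702 of 3248 (21.6%) over all protein-coding genes. The difference was not tested. The 15 genes include 1 each from the pancreas, neuron, lymphocyte, adrenal cortex and erythroid lists. Slc6a19, a neutral amino acid transporter gene of the proximal tubule, had signals of 11.4 and 6.49 in replicates 1 and 2 at a start 12.6 kb from its 5′ end. Slc34a1, the phosphate cotransporter gene, had 2.92 and 2.47 at 1.51 kb, and Ppargc1a, a coactivator gene of mitochondrial metabolism, 4.10 and 4.28 at 13.9 kb. The tight junction gene Cldn10 had 1.24 and 0.876 at 66.8 kb, the sodium-calcium exchanger gene Slc8a1 0.669 and 0.594 at 68.2 kb, and the cell cycle inhibitor gene Cdkn1a 5.24 and 4.56 at 2.79 kb.

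Loci of Hox paralogs 9 to 11 had few replicate 2 peaks. With the same number of top peaks from each library, observed over expected was 0.360 (single random lists 0.633 to 1.33), the lowest of 27 lists in that comparison, and with the expectation set by GC content it was 0.424 (0.689 to 1.43), no nearer to 1 than the 0.486 without it. Replicate 1 peaks there were also found in replicate 2 less often than peaks of the same signal, with a ratio of 0.453 (0.682 to 1.18), and of 0.439 (0.669 to 1.16) for the same signal and GC content, so these values argue against depth, weak signal or GC content as the whole cause. Chance stays open: the list was picked for its low value, neighbouring genes share peaks, and over 27 lists the adjusted permutation p was 0.158 and 0.127 in the first comparisons and 0.0387 and 0.0369 in those by signal, where paralogs 1 to 8 had the same p (ratios 0.693 and 0.678) and adrenal cortex genes passed in the other direction (1.70 and 1.64, p = 0.0108). Over cluster segments of paralogs 9 to 11, 18 replicate 2 peaks stood against 56, a ratio that 0 of 10000 sets of windows reached. With GC content the ratio was 0.315 (0.03% of sets). Segments of paralogs 1 to 8 had 0.65, with 33.0% of sets at or below. By cluster, from Hoxa to Hoxd, 15.2%, 0.798%, 0.846% and 2.99% of windows were at or below the 9 to 11 segment. For the 1 to 8 segments these shares were 99.8%, 8.50%, 0.408% and 9.28%. The windows are no independent support, since the segments hold the genes of the list picked for its low value. No biological explanation was tested, since the design holds 1 group.

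Weaker signal on chromosome X was not explained by the CpG content of its promoters. Over autosomal promoters nearest in CpG (50 for each X promoter), the ratio of median promoter signal was 0.555 (bootstrap 95% interval 0.487 to 0.632) in replicate 1 and 0.648 (0.550 to 0.696) in replicate 2, both below the 0.75 set for CpG content alone. Among genes of the highest CpG tertile it was 0.592 (0.456 to 0.678) and 0.616 (0.549 to 0.783). The mean of the latter pair, 0.604, lies near what 1 copy could give, but replicate 2 fell outside the range set for 1 copy, 0.4 to 0.6, so the single copy stays open. No biological explanation was tested beyond it.

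Replicate 2 had few peaks in AT-rich DNA relative to replicate 1. Replicate 1 had 5.32 times as many peaks in the most AT-rich of 20 bins and 1.17 times as many in the most GC-rich. Over all bins the libraries had 169994 and 91750 peaks. Lower depth of replicate 2 is unlikely to be the whole cause, because GC-rich peaks overlapped replicate 2 more often, by over 2 percentage points, in 8 of 10 deciles of replicate 1 signal. These gaps were small beside the range over bins without regard to signal, from 22.1% to 81.7% of replicate 1 peaks overlapping. In decile 6 the shares were 56.8% above the median GC content and 47.2% below it. The bins split GC content more finely, so how much of the contrast depth explains stays open. A GC preference of the libraries stays open: over shared peaks in the top 3 deciles of signal the rank correlation of the log2 signal ratio with GC content was −0.0740, weaker than the bound of −0.1 set beforehand, and over all shared peaks it was 0.0478, but within deciles of signal it was below −0.1 in 7 of 10, and the pooled values mix levels of signal. No biological explanation was tested.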
